A study of Homo sapiens with 6 samples.

How the data were processed

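Total RNA from MDA-MB-231 cells was labelled with biotin for whole-transcript cartridge arrays, per the labels' protocols, after growth in medium with 10% serum and 2.5 µg/ml puromycin. The deposited table holds one normalized intensity per probe set and array on a linear scale. Per the submitters' processing notes it was made with Transcriptome Analysis Console; its version, and the background correction, summarization and normalization methods, are not given in the sources used here. The log2 of every deposited intensity ended at 5 decimal places (largest deviation 7.13e-10), so the values had been on a log2 scale before deposit. The table has no detection calls, scanner flags or scan dates, so no probe set could be called below background and no batch could be tested.

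The table covers 16965 probe sets on 6 arrays. The platform annotation gave 15674 of them 1 gene symbol, 0 several and 1291 none; a probe set without a symbol is unnamed here, not without a gene. All 15674 were matched by gene identifier to the RefSeq table of assembly GRCh38.p14, which changed 0 symbols, and this table was used for names, gene span and the order of neighbouring genes. The array's own genome build was not named, so no coordinates are given.

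Samples were grouped by their titles into shNCT, shS100A10_1 and shS100A10_5 with 2 arrays each. Intensities were converted to log2 with no further normalization. A linear model with a mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups share one estimate of the spread (3 residual and 7.16 prior degrees of freedom, prior SD 0.194 log2). The contrasts, tested in both directions, were each hairpin against the control, shS100A10_5 against shS100A10_1, and the mean of both hairpins against the control. P-values were adjusted by Benjamini-Hochberg over all 16965 probe sets, with 0.05 as the threshold.

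Named genes followed a rule set before the data were examined. It took S100A10 and ANXA2 always. For each hairpin it took the 8 largest rises and 8 largest falls past the threshold whose hairpin arrays did not overlap the controls, and for both hairpins up to 10 shared rises and 10 shared falls. It also took the 4 largest differences each way between the hairpins, and from each gene list the 4 members with the smallest p for the mean of both hairpins, whether or not they passed. Symbols of small RNAs, uncharacterized loci and open reading frames were not named but stay in the counts.

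Of 43 gene lists fixed before the data were examined, 42 had at least 3 measured members and 1 had none. They were tested with limma's camera with a preset correlation of 0.01 between genes, on 1 probe set per gene (the brightest over all arrays), adjusted over the lists. Camera with an estimated correlation and fry stand beside it. With the estimated correlation, 0 of the 42 lists passed in any comparison. That version of camera tests on the 3 residual degrees of freedom, far fewer than the preset version uses, so few lists could pass it here. For DNA replication with shS100A10_5 the estimated correlation of 0.011 was close to the preset, yet the unadjusted camera p was 0.0056 against 4.2e-13. A list not passing it therefore does not by itself show that correlation between genes explains its call. Fry, which tests whether a list's genes move one way on balance, passed 0 lists for shS100A10_1, 6 for shS100A10_5, 6 for the difference and 3 for the mean. Those 6 were DNA replication and cholesterol synthesis, lower, and NRF2, ATF4, immediate early and Notch genes, higher, in both comparisons. For the mean they were DNA replication, cholesterol synthesis and NRF2. Interferon (fry adjusted p = 0.0509), glycolysis (0.0696), oxidative phosphorylation (0.204), histones (0.274) and ribosomal proteins (0.286) passed camera for shS100A10_5 but not fry.

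Shared calls were compared with 100 simulated data sets of unchanged groups that share 2 controls, drawn with the fitted variances. The fit was tested on simulated data with 200 changed probe sets among 16965. For shS100A10_1 it recovered 7.73% of changes of 0.5, 85.6% of changes of 1 and 100% of changes of 2 on the log2 scale, with 6.35% false calls. For shS100A10_5 these shares were 5.28%, 84.4% and 100%, with 6.96% false calls. With genes drawn independently of each other, the list test made 0 false calls in 20 unchanged data sets for shS100A10_5. It found a list shifted by -0.3 in all 20. Such data sets cannot show the false calls that correlated genes would give. The estimated correlation was 0.71 for ribosomal proteins, 0.57 for histones and 0.54 for oxidative phosphorylation, but 0.01 for DNA replication and 0.02 for interferon-stimulated genes.

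Alternatives were quantile normalization, median centring, filters on dim probe sets, an intensity trend or robust hyperparameters in eBayes, array weights, the replicate number as a block, fits with only the groups compared, 1 probe set per gene, other thresholds, an unmoderated two-group test, other list tests, and leaving out each array. A trend on gene span and the test of the lists on the difference between hairpins were added after the data were seen. No sample was left out of the fits reported first.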

Results

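Gene expression was measured on 6 arrays of total RNA from MDA-MB-231, an established human triple-negative breast cancer cell line. The cells carried a lentiviral short hairpin RNA, either a control hairpin (shNCT) or 1 of 2 hairpins directed against S100A10 (shS100A10_1 and shS100A10_5), with 2 arrays in each of the 3 groups. S100A10 encodes p11, a small protein of the S100 family that pairs with annexin A2 at the plasma membrane and binds plasminogen. Median intensity lay between 232 and 238 on all 6 arrays. The SD of the log2 difference between the 2 arrays of a group was 0.287 for shNCT, 0.292 for shS100A10_1 and 0.360 for shS100A10_5, and no pair of arrays held identical columns. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and their small number limits the precision.

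The first principal component of the log2 values, with 45.2% of the variance, separated both shS100A10_5 arrays from the other arrays. Replicate 2 of shS100A10_5 lay farthest out, at 41.1 against 18.7 for replicate 1, while the 4 other arrays lay between -18.2 and -10.0. The second component, with 19.8% of the variance, separated shS100A10_1 from shNCT.

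**Figure D1:**
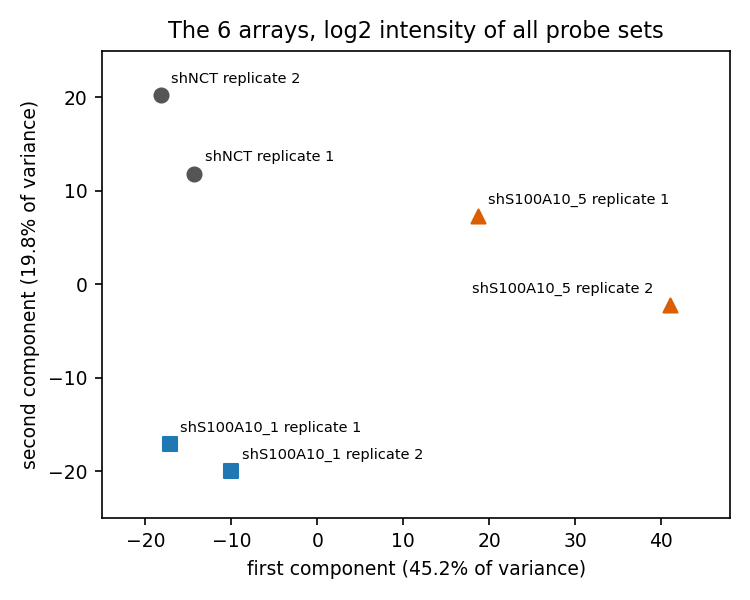
Positions of the 6 arrays on the first principal component (x axis, 45.2% of the variance) and the second (y axis, 19.8%) of log2 intensity over all 16965 probe sets; each point is 1 array, with circles for shNCT, squares for shS100A10_1 and triangles for shS100A10_5. The shS100A10_5 arrays sit at 18.7 and 41.1 on the first component, and the other 4 arrays at or below -10.0.

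The targeted gene was read first. S100A10 intensity was 88860 and 92938 on the control arrays, 1969 and 1545 with shS100A10_1, and 13565 and 9461 with shS100A10_5. On the log2 scale the control level was 16.47 ± 0.05 (SD, n = 2), and it fell by 5.70 (SE 0.21) to 10.77 ± 0.25 with shS100A10_1, a 52.1-fold lower intensity (limma, adjusted p = 1.71e-06). With shS100A10_5 it fell by 3.004 (SE 0.21) to 13.47 ± 0.37, or 8.02-fold (limma, adjusted p = 0.000442). The remaining S100A10 signal was 6.49-fold higher with shS100A10_5 than with shS100A10_1, and that difference was itself past the threshold (limma, adjusted p = 0.00102). ANXA2, which encodes the annexin A2 partner, had log2 changes of -0.04 and -0.05 (SE 0.17 each; limma, adjusted p = 0.978 and 0.891).

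With shS100A10_1, the largest rise was that of TNFSF15, a cytokine of the tumour necrosis factor superfamily, by 2.60 on the log2 scale (SE 0.17, 6.05-fold). It was followed by the interferon-induced antiviral gene OASL (2.50), AGMO, whose enzyme cleaves ether lipids (2.26), the membrane trafficking gene MAL2 (2.20), and IFIT2, another interferon-induced gene (2.04). AGR2, a protein disulfide isomerase of the endoplasmic reticulum, rose by 2.005, the cysteine protease inhibitor gene CST1 by 1.84 and the adhesion gene MPZL2 by 1.80. Apart from S100A10, the largest falls were those of LCTL, a klotho-family member (log2 change -2.01), GYG2, a glycogenin that primes glycogen synthesis (-1.89), DENND6A (-1.86), CST7, which encodes cystatin F (-1.77), the sphingosine-1-phosphate receptor gene S1PR1 (-1.70), CPA3, a carboxypeptidase of mast cells (-1.56), and UMAD1 (-1.51). All of these had SEs between 0.17 and 0.30, with limma adjusted p between 0.00027 and 0.0316. By the naming rule, none overlapped between the 2 hairpin and 2 control arrays, which held for 7191 of all 16965 probe sets.

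In all, 32 of 16965 probe sets changed with shS100A10_1 (limma, adjusted p under 0.05), 17 higher and 15 lower, each by at least 2-fold. At an unadjusted p under 0.05 there were 1432, against 848 by chance. For all 32 the hairpin and control arrays did not overlap, so leaving out 1 array could not change their sign. Leaving out any array lowered the count: it was 9 and 8 without shNCT replicates 1 and 2, 13 and 15 without shS100A10_1 replicates 1 and 2, and 16 without either shS100A10_5 array, although all 32 kept their sign. TNFSF15, OASL, AGMO, MAL2, AGR2, CST1 and MPZL2 stayed past the threshold whichever array was left out. Across the other settings the count ran from 16 with only the groups compared in the fit to 98 with an intensity trend in the variance prior. An unmoderated two-group test gave 0, but with 2 arrays per group hardly any probe set could pass it.

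The list of interferon-stimulated genes shifted up with shS100A10_1. Of the 34 measured, 29 had a positive change, and the median was 0.29; OASL and IFIT2 passed over all genes and 7 passed adjusted over the list alone (limma camera, adjusted p = 3.24e-09, and adjusted p = 0.447 with an estimated correlation). The list of NF-kB targets and cytokines shifted up with a median of 0.20 (adjusted p = 0.0255, and adjusted p = 0.677 with an estimated correlation). None of its 23 members passed over all genes by limma, 7 were higher and 1 lower at an unadjusted p under 0.05, and 6 passed adjusted over the list alone. Genes of MHC class I antigen presentation shifted up by a median of 0.33 over 13 members, among them TAPBP (0.72, limma adjusted p = 0.304) and TAP1 (0.38, adjusted p = 0.641), with a limma camera adjusted p = 0.0378 for the list, and adjusted p = 0.677 with an estimated correlation. Genes of DNA replication (median -0.09, 33 measured) and replication-dependent histones (median -0.13, 25 measured) shifted down, both with an adjusted p of 0.0378, and with adjusted p = 0.677 and 0.886 with an estimated correlation. No member of the MHC class I, replication or histone lists passed limma's threshold over all genes or adjusted over the list alone. At an unadjusted p under 0.05 by limma, 3 of the first were higher, 4 of the second lower and 0 of the last changed. The histone median shrank to -0.07 without shNCT replicate 2 and to -0.04 without shS100A10_1 replicate 2. The interferon call held without each array in turn, while NF-kB was lost without shNCT replicate 1 (adjusted p = 0.113) or shS100A10_1 replicate 2 (0.125), and histones without shNCT replicate 2 (0.561) or shS100A10_1 replicate 2 (0.861), with medians of -0.24 without shNCT replicate 1 and -0.28 without shS100A10_1 replicate 1. MHC class I and DNA replication were lost without shNCT replicate 1 (0.256 for both), shNCT replicate 2 (0.0514 and 0.102), shS100A10_1 replicate 1 (0.293 and 0.381) or shS100A10_1 replicate 2 (0.079 and 0.067).

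With shS100A10_5, SLITRK6, which encodes a neuronal transmembrane protein, rose by 2.68 on the log2 scale (SE 0.25, 6.40-fold), and CMKLR1, the chemerin receptor gene, by 2.47 (SE 0.17, 5.56-fold). The circadian repressor gene NR1D1 rose by 2.30, the kinase gene MAP3K13 by 1.90, ID2, an inhibitor of basic helix-loop-helix factors, by 1.77, SNAI1, a transcriptional repressor of E-cadherin, by 1.75, and ARRDC4 and SYT1 by 1.71 each. Apart from S100A10, the largest falls were those of QPCTL, a glutaminyl cyclase of the Golgi (log2 change -2.17), the mesothelin gene MSLN (-1.91), CMTM3 (-1.82), the histone genes H4C1 (-1.77) and H2AC21 (-1.68), the aminoacylase gene ACY1 (-1.63) and HCFC1R1 (-1.58). These had limma adjusted p between 0.000442 and 0.0338. The control levels of SLITRK6 (log2 3.77) and ID2 (4.92) lay below 4.98, the lower quartile of the probe set means.

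In all, 539 probe sets changed with shS100A10_5 (limma, adjusted p under 0.05), 242 higher and 297 lower, and 263 of them by at least 2-fold; with each array centred on its median the split was 244 higher and 235 lower. This count depended on single arrays: without shS100A10_5 replicate 2, the array farthest out on the first component, 3 probe sets passed, while 994 passed without replicate 1, 22 without shNCT replicate 1 and 12 without shNCT replicate 2. All 539 kept their sign in each of these fits, and of the 15 genes named above other than S100A10, only CMKLR1 and NR1D1 passed without replicate 2, 8 without shNCT replicate 1 and 6 without shNCT replicate 2. The signs of the 539 could not change in these fits, since their hairpin and control arrays did not overlap. Across the other settings the count ran from 242 with array weights to 1454 with an intensity trend. An unmoderated two-group test gave 0, but with 2 arrays per group hardly any probe set could pass it.

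The list of DNA replication and E2F genes shifted down with shS100A10_5. Of 33 measured, 31 had a negative change, with a median of -0.61; 5 fell over all genes and 20 adjusted over the list alone (limma camera, adjusted p = 1.77e-11, and adjusted p = 0.237 with an estimated correlation). E2F1 itself fell by 1.35, the thymidine kinase gene TK1 by 1.03 and the GINS complex gene GINS1 by 0.88, while the helicase gene MCM2 had a change of -0.72 (limma adjusted p = 0.0532). Replication-dependent histones shifted down with a median of -0.35 over 25 genes, 2 of which fell over all genes and 8 adjusted over the list alone (adjusted p = 0.00036, and adjusted p = 0.696 with an estimated correlation). These 2 were H2AC11 (-1.16) and H2AC4 (-1.10), and the falls of H4C1 and H2AC21 given above are not counted among them.

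Metabolic lists also shifted down with shS100A10_5. The 21 nuclear genes of oxidative phosphorylation had a median of -0.46, and 6 fell adjusted over the list alone (limma camera, adjusted p = 0.00015, and adjusted p = 0.648 with an estimated correlation); none passed over all genes by limma, and 11 were lower and 1 higher at an unadjusted p under 0.05. All 18 glycolysis genes had a negative change, with a median of -0.26, PFKL (-1.05) past the threshold over all genes and 3 adjusted over the list alone (adjusted p = 0.00036, and adjusted p = 0.648 with an estimated correlation). The 17 cholesterol synthesis genes had a median of -0.47, with MVK, the mevalonate kinase gene, lower by all-gene adjustment (-1.19) and 9 lower adjusted over the list alone (adjusted p = 0.00143, and adjusted p = 0.603 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.24 over 27 members (adjusted p = 0.00143, and adjusted p = 0.798 with an estimated correlation), none past limma's threshold singly, with 6 lower at an unadjusted p under 0.05. FASN (-0.89) and ACSS2 (-0.95), of fatty acid synthesis, fell as single genes, but their list of 11 did not pass (adjusted p = 0.0794).

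Interferon-stimulated genes shifted up with shS100A10_5 as well, with 27 of 34 positive and a median of 0.25 (limma camera, adjusted p = 0.00106, and adjusted p = 0.610 with an estimated correlation). The 3 members that rose over all genes included XAF1 (1.22) and OAS1 (1.13), and 9 rose and 1 fell adjusted over the list alone. Without shS100A10_5 replicate 2, the calls held for DNA replication (median -0.49, adjusted p = 7.1e-12), cholesterol synthesis (-0.34, 0.00578), glycolysis (-0.20, 0.00578), interferon (0.27, 0.00578) and oxidative phosphorylation (-0.31, 0.0388). They were lost for histones (-0.25, 0.081) and ribosomal proteins (-0.08, 0.204), and without replicate 1 the median for oxidative phosphorylation was -0.74. The deviation of that array from the mean of all arrays rose with gene span (Spearman's rho across genes 0.247, against 0.035 for replicate 1, -0.207 and -0.007 for shS100A10_1 replicates 1 and 2, and -0.135 and -0.061 for shNCT replicates 1 and 2), and genes are not independent replicates. With a smooth trend on gene span removed from each array, a setting chosen after seeing the data, the 7 lists all remained past the threshold, the weakest being ribosomal proteins (adjusted p = 0.0372).

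**Figure D2:**
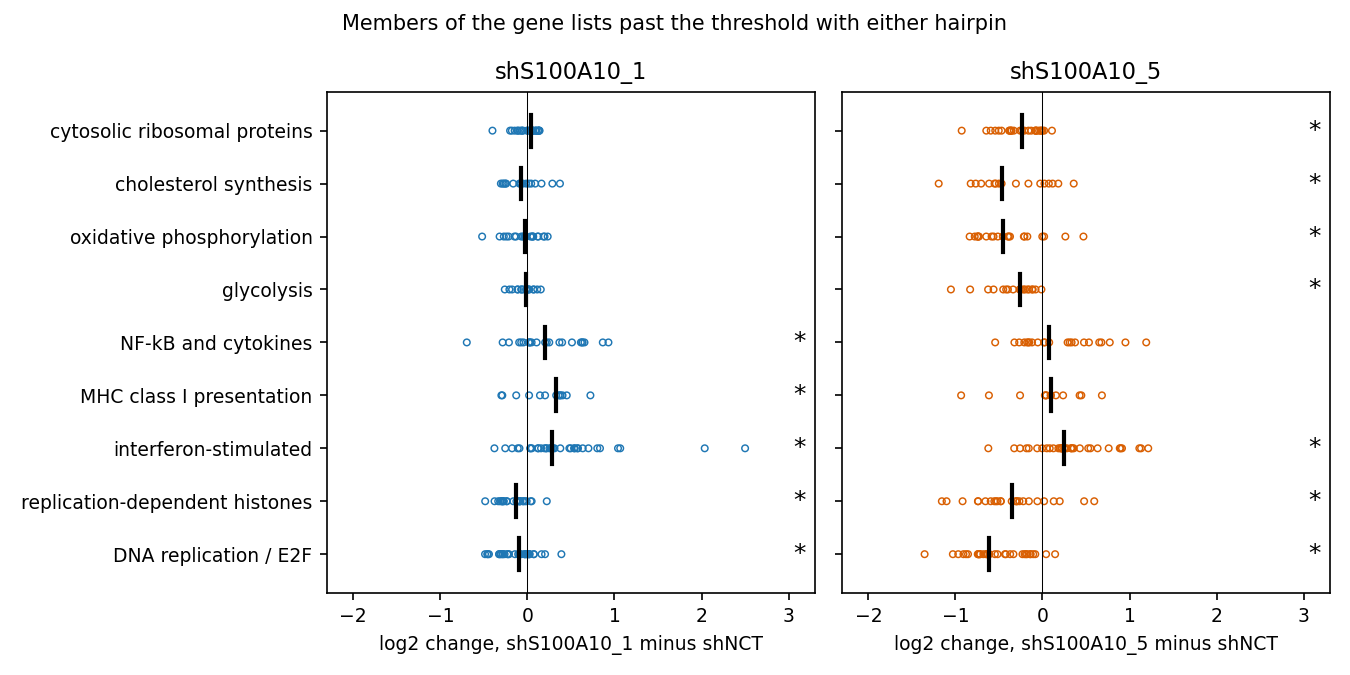
Log2 change of each measured member (open circles) of the 9 gene lists past the threshold with either hairpin, with shS100A10_1 minus shNCT on the left x axis and shS100A10_5 minus shNCT on the right; black bars are list medians and an asterisk marks a limma camera adjusted p under 0.05. The DNA replication list has a median of -0.09 on the left and -0.61 on the right, and the interferon list 0.29 and 0.25.

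Genes named from lists that did not pass limma camera for shS100A10_5 also changed with it. NUPR1 (1.45), SLC7A11, the cystine transporter gene (1.28), ATF3 (1.42), GDF15 (1.21), JUNB (1.36), the Notch target HES1 (1.39) and RNF43 (1.10) rose. The cyclin-dependent kinase inhibitor gene CDKN1A (-1.57), JUN (-0.79), PCK2 (-0.92), LAMB1 (-0.86), LAMB2 (-1.005) and UBE2C (-0.76) fell. ITGA2, an integrin subunit for collagen, rose by 1.31, ICAM1 by 1.19 and AGO3, of the RNA interference machinery, by 0.84. These had limma adjusted p between 0.00818 and 0.0484, and all of them rest on the fit that includes replicate 2.

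Both hairpins changed 13 probe sets in the same direction, and none in opposite directions. S100A10 and CPA3 fell, with CPA3 lower by 1.06 with shS100A10_5 (log2 change -1.06). The 11 shared rises included AGMO (2.26 with shS100A10_1 and 1.55 with shS100A10_5), AGR2 (2.005 and 1.48), CMKLR1 (1.37 and 2.47), the lysozyme gene LYZ (1.56 and 1.35), MPZL2 (1.80 and 1.33) and CST1 (1.84 and 1.23). The others were MAL2 (2.20 and 1.23), the kynureninase gene KYNU (1.38 and 1.21), the cystatin gene CST4 (1.35 and 1.15), TNFSF15 (2.60 and 1.08) and PLAAT4 (1.28 and 1.06), which the naming rule did not take and which was added after its values were seen. CST1 and CST4 are close paralogs, and signal shared between their probes could not be separated. AGR2 was the 1 gene past the threshold among 12 luminal breast markers, whose median change was -0.08 with shS100A10_1 and 0.04 with shS100A10_5, and LYZ was the 1 among 10 leukocyte markers, whose medians were 0.14 and 0.07.

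**Figure D3:**
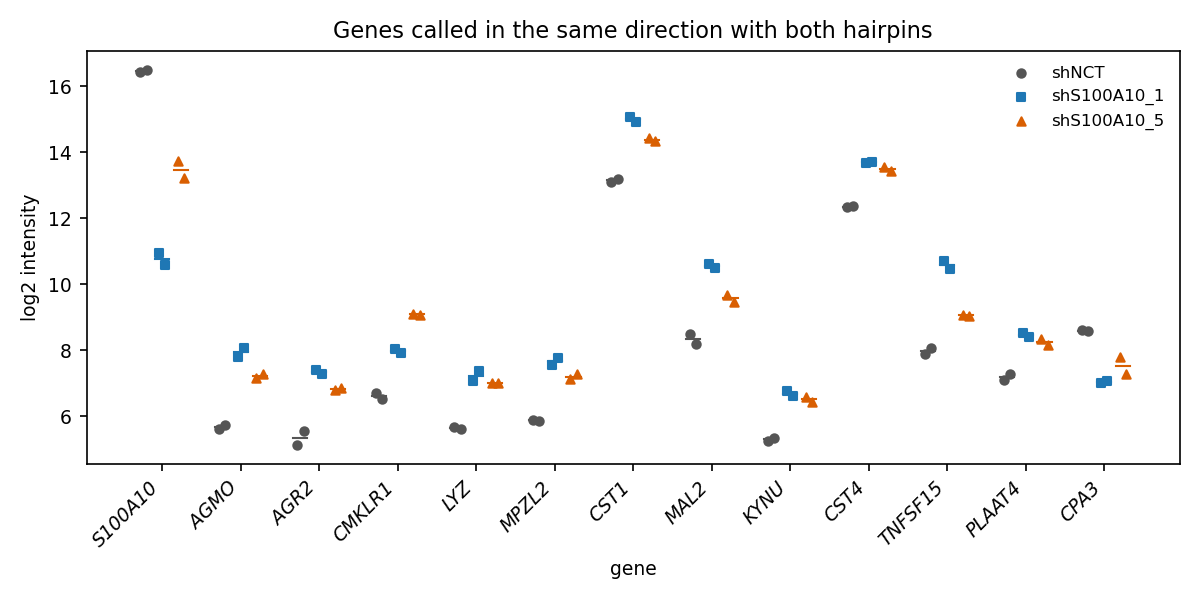
Log2 intensity on each array (y axis) for the 13 genes called in the same direction with both hairpins (x axis), with 2 points per group and a short line at the group mean; circles are shNCT, squares shS100A10_1 and triangles shS100A10_5. In S100A10 and CPA3 both hairpin groups lie below the controls, and in the other 11 genes they lie above.

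Independent lists of these sizes would share 0.242 rises and 0.263 falls. In 100 simulations of unchanged groups measured against the same 2 controls, the largest number of shared calls was 0, with 0.15 calls on average for shS100A10_1 and 0.09 for shS100A10_5. With 2 controls, part of the excess may come from the control arrays that both comparisons share. Where only 1 stayed shared with an array left out, it was S100A10, the targeted gene itself, and none of the other shared genes. The number shared was 1 without shNCT replicate 1, 2 without shNCT replicate 2, 8 without either shS100A10_1 array and 1 without shS100A10_5 replicate 2.

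Over all probe sets, the changes with the 2 hairpins correlated with r = 0.385 (Spearman's rho 0.387), across genes that are not independent replicates. Shared controls alone gave a mean r of 0.4996 in the simulation. The observed covariance was 0.0399 against a simulated 0.0206 (SD 0.0003), a difference of 0.0194. The same sign was seen for 64.4% of probe sets, against 66.7% in the simulation. Of the 32 probe sets called with shS100A10_1, 22 had the same sign with shS100A10_5, and of the 539 called with shS100A10_5, 428 had the same sign with shS100A10_1.

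**Figure D4:**
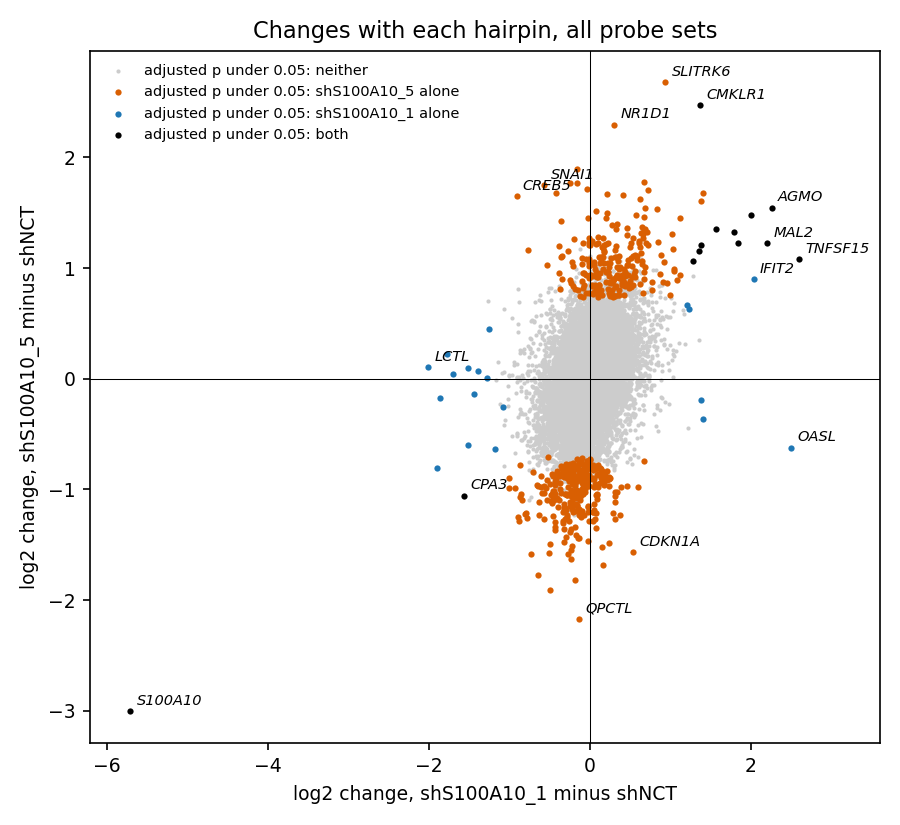
Log2 change of each of the 16965 probe sets with shS100A10_1 (x axis) and shS100A10_5 (y axis), both minus shNCT; black points passed the threshold with both hairpins, blue with shS100A10_1 alone, orange with shS100A10_5 alone and grey with neither. S100A10 lies at -5.70 and -3.004, and OASL at 2.50 and -0.62.

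The hairpins differed from each other in many genes. OASL was lower with shS100A10_5 than with shS100A10_1 by 3.12 on the log2 scale (difference -3.12, SE 0.18; limma, adjusted p = 0.000147), since it rose with shS100A10_1 and had a change of -0.62 (adjusted p = 0.0928) with shS100A10_5. CDKN1A (-2.11), QPCTL (-2.03) and H2AC21 (-1.84) were also lower with shS100A10_5. CREB5 (2.56), SNAI1 (2.31) and LCTL (2.11) were higher, after S100A10 itself (2.70). In all, 494 probe sets differed, 243 higher and 251 lower with shS100A10_5, and these included 18 of the 32 changed with shS100A10_1 and 234 of the 539 changed with shS100A10_5. The count was 7 without shS100A10_5 replicate 2, 83 and 131 without shS100A10_1 replicates 1 and 2, and 291 without either control; OASL, SNAI1 and S100A10 passed in all 6 of these fits.

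Tested on that difference, a comparison added after seeing the data, 5 lists were lower with shS100A10_5 and 1 higher. DNA replication differed by a median of -0.43 (limma camera, adjusted p = 5.24e-07, and adjusted p = 0.470 with an estimated correlation), oxidative phosphorylation by -0.44 (0.000833, and adjusted p = 0.693 with an estimated correlation) and glycolysis by -0.24 (0.00145, and adjusted p = 0.656 with an estimated correlation). Ribosomal proteins differed by -0.21 (0.00145, and adjusted p = 0.830 with an estimated correlation) and cholesterol synthesis by -0.25 (0.0094, and adjusted p = 0.571 with an estimated correlation). The list of ATF4 and integrated stress response genes was higher by a median of 0.22 (0.00511, and adjusted p = 0.571 with an estimated correlation), with NUPR1 (1.47) and SLC7A11 (1.18) among its 3 members past the threshold. Interferon-stimulated genes as a list had a median difference of -0.01 (adjusted p = 0.679). Without shS100A10_5 replicate 2, oxidative phosphorylation (adjusted p = 0.119) and ribosomal proteins (0.247) no longer passed, and without replicate 1 the ATF4 list did not (0.0823). The median for cholesterol synthesis was -0.41 without shS100A10_5 replicate 1 and -0.39 without replicate 2. For ribosomal proteins it was -0.32 without replicate 1 and -0.08 without replicate 2. For oxidative phosphorylation these medians were -0.62 and -0.21, and for the ATF4 list 0.21 and 0.28.

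The labels also set both hairpins together against the control. The mean of both differed from shNCT in 52 probe sets (limma, adjusted p under 0.05), 40 higher and 12 lower; the split was 69 and 71 without probe sets below the median signal, and 117 and 101 with an intensity trend. Besides the shared genes, the rises included AKR1C1, an aldo-keto reductase and NRF2 target (1.54), IFIT2 (1.47), ITGA2 (0.97), OASL (0.94), JUNB (0.91), ICAM1 (0.91) and PLAT, the gene of tissue plasminogen activator (0.88), with limma adjusted p between 0.0153 and 0.048. Further rises and the falls are not listed here. OASL passes here although its changes with the 2 hairpins differ in sign. The count was 6 and 7 without shNCT replicates 1 and 2, 31 without shS100A10_1 replicate 2, and 11 and 10 without shS100A10_5 replicates 1 and 2. Of the 42 lists, 7 passed for this mean: interferon (0.34, adjusted p = 5.99e-09) and NF-kB (0.13, 0.0358) upward, and DNA replication (-0.33, 2.2e-09), histones (-0.30, 0.000346), oxidative phosphorylation (-0.22, 0.00391), glycolysis (-0.13, 0.00902) and cholesterol synthesis (-0.26, 0.0117) downward. With an estimated correlation their adjusted p lay between 0.244 and 0.708. NF-kB was lost without shNCT replicate 1 (adjusted p = 0.0938), shS100A10_1 replicate 2 (0.0535), shS100A10_5 replicate 1 (0.061) or shS100A10_5 replicate 2 (0.113), cholesterol synthesis and glycolysis without shNCT replicate 1 (0.0541 and 0.0938), and oxidative phosphorylation without shS100A10_5 replicate 2 (0.0979). The median for histones was -0.16 without shNCT replicate 2, and for glycolysis -0.20 without shS100A10_5 replicate 1. For oxidative phosphorylation it was -0.13 without shS100A10_5 replicate 2, and for NF-kB 0.23 without shS100A10_1 replicate 2.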

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

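The genes and lists given first stand out because the 2 hairpins differed from each other, by limma's test of the difference for single genes and by camera for lists. The last paragraph of this part takes up the probe sets changed in the same direction with both. The list test on the difference, the tests of a graded response, and those of replicate 1, the exchanged control arrays, the control cultures and the luminal list were chosen after the results were seen. Of 191 named genes, 41 differed, and of 42 lists 6. Lower with shS100A10_5 than with shS100A10_1, as log2 differences, were OASL (-3.12), CDKN1A (-2.11), QPCTL (-2.03), H2AC21 (-1.84), CMTM3 (-1.63), TNFSF15 (-1.52), MSLN (-1.41), ACY1 (-1.39), HCFC1R1 (-1.31), PFKL (-1.13), MVK (-1.10), E2F1 (-1.03), MMP1 (-1.02), ACSS2 (-1.01), MAL2 (-0.98), FASN (-0.88), LAMB2 (-0.83) and NDUFV1 (-0.80). Higher were TFF1 (0.88), JUNB (0.89), SYT1 (0.98), XAF1 (1.02), HES1 (1.06), GYG2 (1.09), CMKLR1 (1.11), SLC7A11 (1.18), GDF15 (1.20), NUPR1 (1.47), DENND6A (1.69), SLITRK6 (1.74), ARRDC4 (1.74), S1PR1 (1.75), ATF3 (1.77), ID2 (1.93), NR1D1 (2), CST7 (2), MAP3K13 (2.06), LCTL (2.11), SNAI1 (2.31), CREB5 (2.56) and S100A10 (2.70). The lists differed by medians of -0.43 (DNA replication), -0.44 (oxidative phosphorylation), -0.24 (glycolysis), -0.25 (cholesterol synthesis), -0.21 (ribosomal proteins) and 0.22 (ATF4 and integrated stress).

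With shS100A10_5, 539 probe sets changed against 32 with shS100A10_1, although S100A10 fell less. A bias by gene span does not account for most of the count, which was 483 after the trend was removed, against 582 over the same genes without that step. Nor did the direction come from 1 array: over the 993 probe sets called without replicate 1, that replicate had a median change of 0.579 in the called direction (interval 0.560 to 0.603 by resampling probe sets), against 1.04 for replicate 2 and 0.162 with shS100A10_1. The size of the count depended largely on shS100A10_5 replicate 2. Fits without replicate 1 and without replicate 2 each lose 1 array of the same group, yet the count rose in the former and fell sharply in the latter. Loss of an array alone thus does not account for it, although the count also fell without either control array. Log2 differences from shNCT replicates 1 and 2 had SDs of 0.476 and 0.504 for replicate 2, against 0.378 and 0.404 for replicate 1. Why replicate 2 stood apart was not tested. A response graded by the loss of S100A10 would give larger changes with shS100A10_1, where the covariance between the changes of its 2 arrays over all probe sets was 0.0309 against 0.0904 with shS100A10_5, but 2 arrays per group leave the spread between arrays open, and effects of the hairpin sequence on other transcripts were not tested.

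OASL and IFIT2 rose with shS100A10_1. A response graded by S100A10 would also raise OASL with shS100A10_5, where its change was -0.62 (95% interval -1.03 to -0.21), while for IFIT2 the change of 0.90 (interval 0.26 to 1.54) is what such a response needs. The 32 other interferon-stimulated genes as a list also shifted up with shS100A10_5, which a response confined to shS100A10_1 would not give. Their median was 0.25, with an interval of 0.20 to 0.35 by resampling genes, which are not independent replicates. The limma camera adjusted p was 0.000511, and with an estimated correlation it was 0.525 (0.677 with shS100A10_1). Both comparisons share the 2 control arrays, so a low control level of these genes cannot be told apart from a rise with both hairpins. The camera adjusted p of 0.953 for the difference in these 32 genes does not settle single members. Of all 34 members, 4 were higher and 9 lower with shS100A10_5 adjusted over the list alone. A response to double-stranded RNA from the hairpins was not tested, since the control carries a hairpin too.

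The 13 probe sets changed in the same direction with both hairpins could reflect the loss of S100A10, which both hairpins share, but this was not tested apart from other causes. With unchanged groups, 0 of 100 simulated draws reached 13 shared calls. Those draws held 0.15 and 0.09 calls on average for the 2 hairpins, so they cannot show what shared control arrays add among real changes. With the trend on gene span removed, 13 were shared, against 15 over the same genes without that step. Both fits keep the same controls and do not bear on this. Chance through shared control arrays is argued against only by calls made and checked with different control arrays, for the few genes they cover. For the shS100A10_1 calls made with shNCT replicate 1 alone, S100A10 left out, the median shS100A10_5 change in the called direction against the other control array was 1.28 (6 of 7 genes in that direction), and with the control arrays exchanged it was 1.22 (7 of 8). An admixture of luminal epithelial cells stays open, as the luminal list had members going both ways around medians of 0.0441 with shS100A10_5 and -0.0826 with shS100A10_1, and its brightest keratins could hide a small share. A difference in the control cultures cannot be told apart from a hairpin effect: the 2 control arrays differed by a median of 0.125 over the 12 genes other than S100A10, and no other control culture was measured.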

How the results depend on the processing

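No log2 change of a named gene past the threshold changed sign under any alternative, but most alternatives could not have changed one. An intensity trend, robust hyperparameters, array weights, the replicate block, dim filters and fits with only the groups compared left the hairpin log2 changes as they were. For every call with either hairpin the hairpin and control arrays did not overlap, so leaving out an array could not reverse its sign. Quantile normalization, median centring and the trend on gene span could have. With each hairpin, S100A10 stayed past the threshold in all fits with limma, with a log2 change between -5.88 and -5.53 with shS100A10_1 and between -3.26 and -2.74 with shS100A10_5 when single arrays were left out. Of 211 results for named genes, 57 were past the threshold and 12 stayed past it in every limma fit. Counting each result once per alternative, 3509 stayed on their side of the threshold, 24 moved past it and 159 no longer passed, while 106 were not tested because a filter on dim probe sets had removed the gene. The trend on gene span, its comparison without the trend, and the shared count with each hairpin fitted alone were chosen after the data were seen. Counts below are given in the order shS100A10_1, shS100A10_5, shared by both, different between hairpins and mean of both, against 32, 539, 13, 494 and 52.

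Without probe sets below the lower quartile of mean signal they were 60, 952, 23, 791 and 85, with 1 list past the threshold for shS100A10_1, and without those below the median 72, 1388, 27, 1039 and 140, where fewer probe sets were tested. With an intensity trend they were 98, 1454, 34, 1144 and 218, and with array weights 89, 242, 21, 287 and 79. With only the groups compared in the fit, 16 changed with shS100A10_1 and 291 differed. With both hairpins as 1 group of 4 against the controls, 0 passed for the mean (limma, with 1268 at an unadjusted p under 0.05), not even S100A10, and so 0 counted as shared in that fit. That fit counts the difference between the hairpins as spread, and for S100A10 this difference was 2.7 on the log2 scale. With each hairpin fitted alone with the controls, 11 were shared. An unadjusted p under 0.05 and at least 2-fold gave 73 and 290 for the hairpins and 283 for the difference. An adjusted p under 0.05 and at least 2-fold gave 263 with shS100A10_5 and 250 for the difference. An unmoderated two-group test with pooled variance gave 0 for all 5 counts at an adjusted p under 0.05. With 2 arrays per group it has so few degrees of freedom that hardly any of 16965 probe sets could pass, so this 0 says little. At an unadjusted p under 0.05, limma gave 1432 and 3564 for the hairpins. Camera with an estimated correlation, which tests on the 3 residual degrees of freedom, gave 0 lists for shS100A10_1, shS100A10_5 and the mean. Fry gave 0 for shS100A10_1 and 3 for the mean. Smaller numbers of probe sets, stricter thresholds, few degrees of freedom and the hairpin difference counted as spread bear on these counts, and other causes were not tested.

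Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, gave 8 to 16 for shS100A10_1, 3 to 994 for shS100A10_5, 1 to 11 shared, 7 to 656 different and 6 to 44 for the mean. The correlation between hairpins ran from 0.29 to 0.52, and lists past the threshold from 1 to 5, 5 to 8 and 4 to 8 for shS100A10_1, shS100A10_5 and the mean. Quantile normalization, median centring, robust hyperparameters, 1 probe set per gene and the trend on gene span kept every count within 1.5 times.

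The balance of rises and falls was less stable: with shS100A10_5 it was 242 and 297, but 244 and 235 with each array centred on its median. It was 15 and 7 without shNCT replicate 1, and 10 and 2 without shNCT replicate 2. The difference between hairpins went from 243 and 251 to 210 and 207 with quantile normalization, and the mean of both from 40 and 12 to 69 and 71 without probe sets below the median signal and 117 and 101 with an intensity trend.

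Same-numbered arrays of shNCT and of each hairpin did not deviate together from their group means (correlations -0.02 and -0.03). Those of the 2 hairpins had a correlation of 0.19, so an effect of the replicate number shared by the hairpin groups stays open. With the replicate block the counts were 33, 625, 15, 561 and 60, and 5, 7 and 7 lists passed. With no detection calls, signal over background could not be set for any probe set.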

Other observations

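The test of neighbouring genes in this part was chosen after the result was seen; the gene lists were fixed before. Lists named for known roles of S100A10 did not pass limma camera with either hairpin. The plasminogen system (12 measured) had PLAT at 0.99 with shS100A10_1 (adjusted p = 0.0647) and past the threshold with shS100A10_5 (0.76, adjusted p = 0.043). Matrix metalloproteinases and their inhibitors (19 measured) had medians of -0.10 and 0.05, with MMP1 at 1.03 with shS100A10_1 (adjusted p = 0.0647) and 0.01 with shS100A10_5. Among 17 genes of the S100 family the medians were 0.07 and -0.02, and among 12 annexins 0.08 and 0.03. Stem cell genes of breast cancer (19 measured) had medians of -0.01 and 0.04 (adjusted p = 0.849 and 0.896), and genes of the epithelial to mesenchymal transition (19 measured) -0.05 and 0.01, with SNAI1 the rise with shS100A10_5. Genes of G2 and mitosis (30 measured) had medians of 0.00 and -0.05 and UBE2C as the 1 member past the threshold with shS100A10_5. NRF2 targets (18 measured) had medians of -0.08 and 0.29, with AKR1C1 higher by 1.68 with shS100A10_5 (adjusted p = 0.00931). With shS100A10_5 their list passed fry (adjusted p = 0.00797) but not limma camera (adjusted p = 0.118).

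Of the genes beside S100A10, THEM4 had changes of 0.06 and -0.11, S100A11 of 0.08 and 0.23, and TDRKH of 0.14 and 0.03, THEM5 of 0.09 and -0.51, and FLG of -0.12 and 1.17 (adjusted p = 0.0577 with shS100A10_5), none past limma's threshold.

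Of the 12 shared genes other than S100A10, 2 pairs lay within 10 measured genes of each other, AGMO with AGR2 and CST1 with CST4. A hypothesis of regional change was tested on the genes between the first pair, since CST1 and CST4 lie side by side with none between. The 5 measured genes between AGMO and AGR2 had median changes of -0.17 with shS100A10_1 and 0.23 with shS100A10_5, and the highest, TSPAN13, had 0.68 and 1.46 (adjusted p = 0.422 and 0.0141). Regional change cannot be told apart from separate responses of AGMO and AGR2, as these 5 genes varied widely, and for CST1 and CST4 signal shared between their probes stays open too. Next to these, CST2 had changes of 1.08 and 0.89 (adjusted p = 0.0668 and 0.0385), and CST3 of -0.06 and -0.57.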
